A study of Rattus norvegicus with 2 samples.

How the data were processed

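RNA from fetal Sprague Dawley rat skin was compared between embryonic day 16.5, which the labels call E16, and embryonic day 18.5, which they call E19. Per the labels, 4 E16 samples were pooled and 3 E19 samples were pooled before hybridisation, RNA was extracted with a NucleoSpin RNA II kit, and it was amplified and labelled with an Agilent Low RNA Input Linear Amp Kit. Both pools were hybridised together to 2 Agilent rat arrays of 45018 spots each. On 1 array the E19 pool carried Cy5 and the E16 pool Cy3, and on the other array the dyes were exchanged. Because both arrays hold the same 2 RNA pools, they were counted as 1 replicate per stage. Both arrays lay on the same slide and were scanned together, so no batch could be tested.

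Per the file headers, spot intensity was measured in each channel with Agilent Feature Extraction 9.5.1.1, and the deposited files give the mean spot intensity and the local median background without correction. Per the file headers, the same program also wrote background-subtracted and dye-normalised intensities, their log10 ratio of Cy5 over Cy3, and a p-value of that ratio from its error model. The authors' deposited table gives a log10 ratio and a p-value for each of 36824 sequences, combined over both arrays by a method not given in the sources used here. Its ratio was read as E19 over E16, because across genes it correlated with the ratio of the array with E19 in Cy5 (r = 0.90) and inversely with the Cy5 over Cy3 ratio of the other array (r = -0.90).

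From the uncorrected intensities, background was corrected with normexp at an offset of 50, and log2 ratios were normalised by loess within each array with control spots at weight 0, using limma 3.58.1 in R 4.3.3. Spots marked as non-uniform or as population outliers were left out, and saturated spots were kept. Each ratio was turned to E19 over E16, spots of the same probe were averaged, and both arrays were averaged, which cancels a dye effect of equal size on both. A probe counted as detected when Feature Extraction placed it well above background for at least 1 of the pools on both arrays. For a gene with several detected probes, the brightest was used. Of 3509 genes with several detected probes, 195 had some but not all probes past the size rule given below, and 0 had probes past it in opposite directions. The 3509 include genes with no probe past the rule, so the 195 are a larger share of those with at least 1 probe past it. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

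Probe names on the array are old and were updated through a RefSeq gene table of the GRCr8 assembly. Of 41012 probes, 10735 were named by accession, 5571 by current symbol and 3727 by a synonym of a single gene, 3371 kept the name in the files, and 17608 had no gene name and entered no gene count. No genome coordinates are given, because the files name no genome build.

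With 1 RNA pool per stage there is no test of the stage difference, and no p-value across genes is given. A gene was called higher at a stage when its ratio was at least 2-fold in that direction on both arrays. The number of genes at least 2-fold towards the same dye on both arrays was counted beside it. Values are the mean log2 ratio E19 over E16 ± the SD of the 2 arrays, which is technical spread and holds nothing of the variation between animals or litters. The number of arrays limits the precision. Where a gene was not well above background in a pool on either array, the brighter pool's level was set against the higher of that probe's own level and the lowest level among well-measured probes, per channel after loess and Aquantile normalisation, and is given as at least N-fold.

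Before the data were examined, 33 gene lists, the size rule, the rule for named genes and most alternative settings were fixed. For each list with at least 5 detected genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn with replacement and matched on mean intensity in 20 bins. A list at or above the 97.5 percentile, or at or below the 2.5 percentile, was called beyond chance. This describes these pools and is not a test between stages. Named genes were the 10 largest ratios in each direction among genes with a symbol that were measured in both pools, up to 4 genes per list with the largest ratios, the 5 brightest genes in each direction measured in only 1 pool, and Gapdh, Actb and sex-linked genes. Not every gene this rule selects is reported here. Other genes named below were chosen after their values were seen.

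The steps were tested on simulated arrays of 41012 probes, of which 200 were changed. At a true log2 ratio of 1.5, 92% of 100 changed probes were recovered, at 3.0 it was 99% of 100, and 0 unchanged probes passed the rule. Changed probes were of middle intensity, noise was normal, and the dye effect was a straight line in intensity plus noise. The real arrays also differ for the brightest genes, so these rates need not hold for them. The noise was set from the typical difference between the 2 arrays, far under 2-fold. The 0 was therefore all but fixed beforehand and gives no rate of false calls for the real arrays. Alternatives covered background correction, normalisation, detection, saturated and outlier spots, the choice of probe, each array alone, the authors' deposited table, other fold limits and other ways to score lists. Further alternatives, centring on spike-in RNAs, leaving out the brightest genes and setting list members to their bounds, were added after seeing the data.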

Results

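Gene expression in fetal rat skin was compared between 2 RNA pools, E16 (day 16.5, 4 samples) and E19 (day 18.5, 3 samples), on 2 dye-swapped arrays. Between 71.5% and 74.3% of spots were well above background in each channel, and at most 15 spots per channel were saturated. In all, 14789 genes were detected, 14063 of them in both pools. Values below are mean log2 ratios of E19 over E16 ± the SD of the 2 arrays, and there is no replicate check of any difference between the stages.

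At E19 the skin pool carried more transcript of fat cell, cornifying epidermis and barrier lipid genes. At E16 it carried more transcript of neuronal, cartilage and Hox genes. Adipoq, which encodes the fat cell hormone adiponectin, was 29.2-fold higher in E19 (4.87 ± 0.14). Fabp7, a fatty acid binding protein of neural progenitors and glia, was 29.2-fold higher in E16 (-4.87 ± 0.30). In all, 613 genes were at least 2-fold higher in E19 on both arrays and 554 were at least 2-fold higher in E16, against 3 genes that were 2-fold towards the same dye on both. Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with r = 0.90 (Spearman's rho = 0.80). These counts depend on the processing. Median centring in place of loess gave 367 higher in E19 and 439 in E16, with 192 towards the same dye and r = 0.60. Feature Extraction's processed signals gave 1014 and 889. Centred on spike-in RNAs in place of all genes, an alternative added after seeing the data, the split was 389 genes higher in E19 and 809 higher in E16.

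**Figure D1:**
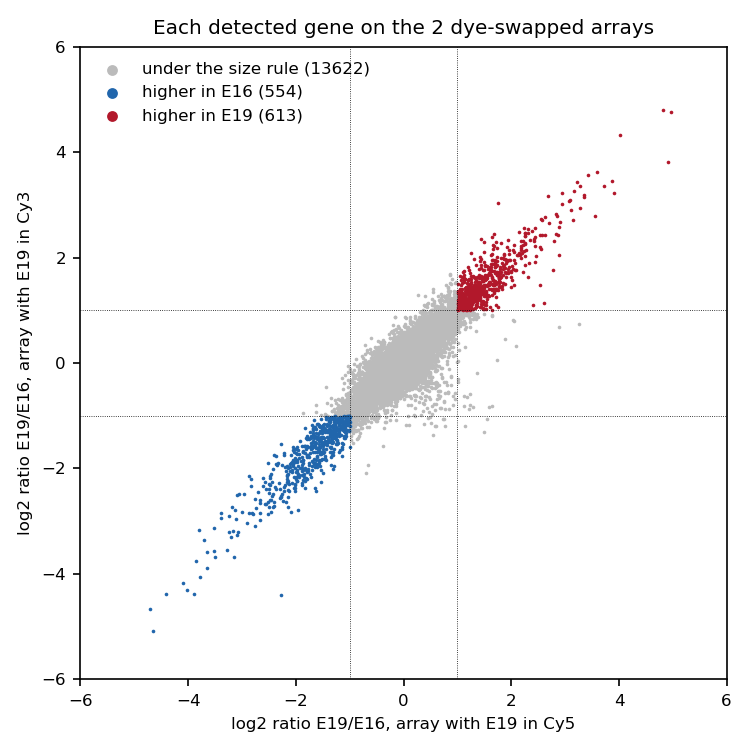
Log2 ratio E19 over E16 of each detected gene on the array with E19 in Cy5 (x axis) and on the array with E19 in Cy3 (y axis), with dotted lines at the 2-fold limits. The 613 genes called higher in E19 lie at the upper right and the 554 called higher in E16 at the lower left, while some genes below the diagonal differ between the dye orientations.

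The largest ratios towards E19 were led by fat cell genes. After Adipoq came Fabp4, the fat cell fatty acid binding protein (4.81 ± 0.01), and Alb, which encodes serum albumin (4.18 ± 0.22). They were followed by Ucp1, the uncoupling protein of brown fat (3.66 ± 0.30), the carbonic anhydrase Car3 (3.60 ± 0.03), the lipid droplet protein gene Cidea (3.57 ± 0.49) and Retn, which encodes resistin (3.54 ± 0.26). The collagenase Mmp13 (3.50 ± 0.10), the iodide transporter Slc5a5 (3.32 ± 0.15) and the stefin Stfa2l1 (3.32 ± 0.06) completed the 10 largest. The largest ratios towards E16 were mostly of genes known from neurons: Chgb of secretory granules (-4.69 ± 0.02), Stmn2 (-4.14 ± 0.35), Nrxn3 (-4.13 ± 0.06), Gpm6a (-3.92 ± 0.20), Iqsec3 (-3.76 ± 0.17), Elavl2 (-3.61 ± 0.05), the neuronal intermediate filament Ina (-3.59 ± 0.13) and Scg3 (-3.55 ± 0.03). Cnmd, which encodes the cartilage protein chondromodulin, was at -4.16 ± 0.19. With Feature Extraction's processed signals Cnmd was at -5.22, Chgb at -5.47, Nrxn3 at -4.84 and Iqsec3 at -4.52. Averaged over all detected probes of the gene, Alb was at 3.19, Gpm6a at -3.02, Iqsec3 at -2.92 and Scg3 at -2.44.

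**Figure D2:**
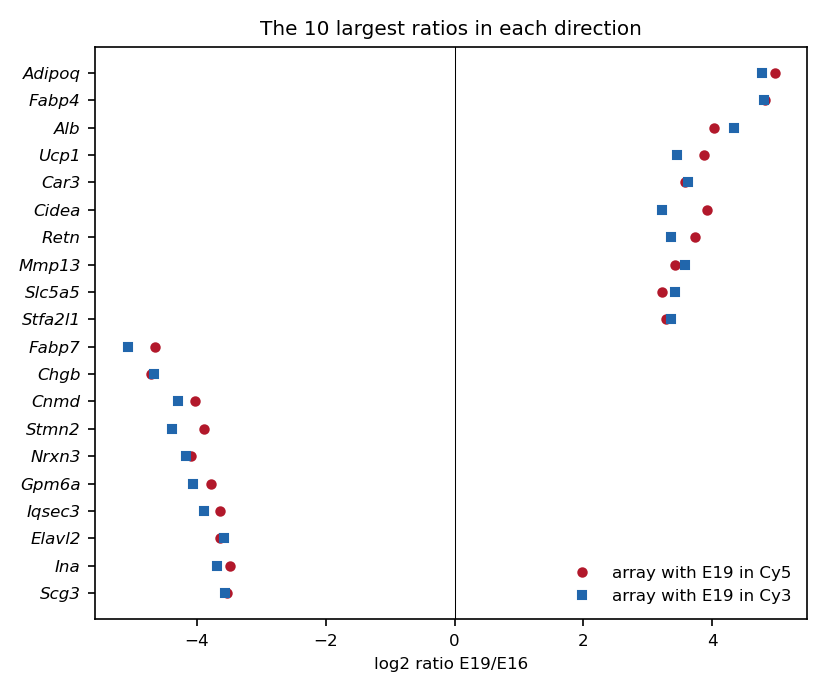
Log2 ratio E19 over E16 (x axis) of the 10 genes with the largest ratio in each direction (y axis), with a circle for the array with E19 in Cy5 and a square for the array with E19 in Cy3. The means run from 4.87 for Adipoq to -4.87 for Fabp7, and both arrays place every gene shown on the same side of 0.

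Cornified envelope and suprabasal keratin genes, which build the outer epidermis, were higher in E19 as a group. Of 35 detected, 24 passed the rule towards E19, and only the keratin Krt77 passed it towards E16 (-1.05). Their median was 1.47, the 100 percentile of matched random lists. The transglutaminase Tgm3, which crosslinks the cornified envelope, had a ratio of 2.65 ± 0.31, the protease Klk7 2.25 ± 0.31, the cystatin Csta 2.19 ± 0.08 and the interleukin 36 receptor antagonist Il36rn 2.09 ± 0.06. Barrier lipid genes had a median of 1.31 (100 percentile), with 11 of 19 higher in E19 and 0 higher in E16. They included the fatty acid elongase Elovl7 (1.90 ± 0.57), Lipm (1.80 ± 0.08), the lipid transporter Abca12 (1.75 ± 0.03) and Abhd5 (1.71 ± 0.04).

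Tight junction and desmosome genes had a median of 0.68 (100 percentile), and 9 of 31 passed the rule, all towards E19. The list also held the gap junction connexins Gjb2 (2.83) and Gjb6 (2.36 ± 0.16), both among the 9. The others included the desmosomal protein gene Dsp (1.70 ± 0.10) and Perp (1.63 ± 0.12). Basal keratinocyte and hemidesmosome genes had a median of 0.58, with 4 of 21 higher in E19, among them Dsc3 (1.94 ± 0.03), the laminin chain Lamb3 (1.13 ± 0.01) and Krt5 (1.11 ± 0.02). Periderm and simple epithelial keratins were within chance (median 0.15), with Krt17 (1.65 ± 0.30) and Krt13 (2.15-fold, SD of the log2 ratio 0.06) past the rule of 13 detected. Some keratins differed between the arrays. Krt1 was at 2.89 on the array with E19 in Cy5 and at 0.69 on the other, so it did not pass the rule.

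Hair shaft and inner root sheath genes had a median of 0.29 (99.1 percentile), but only 4 of 17 passed the rule. Krt33a (2.01 ± 0.75), Crym (1.41 ± 0.43) and Krt25 were higher in E19, and the homeobox gene Msx1 was higher in E16 (-1.36 ± 0.02). Krt25 was well above background in the E16 pool on only 1 of 2 arrays, and its ratio was 1.09 in the main setting, 1.74 at normexp offset 0 and 2.52 with Feature Extraction's processed signals. Hair placode and follicle signalling genes were within chance (median 0.17, 96.6 percentile). Of 28, the follicle transcription factor Lhx2 was higher in E19 (1.99 ± 0.13), and the WNT inhibitor Dkk4 (-1.62 ± 0.06) and the BMP inhibitor Nog (-1.21 ± 0.07) were higher in E16. Melanocyte genes had a median of 0.54, with the pigment genes Tyrp1 (1.63 ± 0.19) and Mlana (1.26 ± 0.16) past the rule of 12 detected.

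Defence genes of the epithelium and cytokines had a median of 0.83 (100 percentile), with 14 of 33 higher in E19. They included the calcium-binding alarm proteins S100a9 (2.82 ± 0.04) and S100a8 (2.70 ± 0.11) and the chemokine Ccl5 (2.35 ± 0.28). S100a8 was at 1.82 averaged over its detected probes. The chemokine Ccl27 (-1.32) and the defensin Defb4 (-1.14) were higher in E16. Mast cell genes had a median of 1.09, and 6 of 12 were higher in E19, among them Hpgds (5.67-fold, SD of the log2 ratio 0.10), the protease Cpa3 (1.47 ± 0.21), the tryptase Tpsb2 (1.34 ± 0.06) and Hdc, which makes histamine (1.19 ± 0.02). Macrophage and other leukocyte genes had a median of 0.56, with Lyz2 (1.64 ± 0.08) and Cd163 (1.62 ± 0.05; 2.51 with Feature Extraction's processed signals) past the rule of 33. Endothelial genes had a median of 0.41 (100 percentile) although 0 of 24 passed the rule. Plvap had the largest of their ratios (0.86 ± 0.11).

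Adipocyte genes had the highest median of the lists (1.79, 100 percentile), with 16 of 25 higher in E19 and 0 higher in E16. Liver and plasma protein genes were also higher in E19, with a median of 1.11 (100 percentile) and 12 of 25 past the rule. Besides Alb, they included the fibrinogen chains Fga (2.41 ± 0.03) and Fgb (2.39 ± 0.04) and the kininogen Kng1 (2.40 ± 0.11). With Feature Extraction's processed signals the median was 1.83, Fga was at 3.13 and Kng1 at 3.53. Ttr, which encodes the thyroid hormone carrier transthyretin, was the single gene of that list higher in E16 (-2.01).

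**Figure D3:**
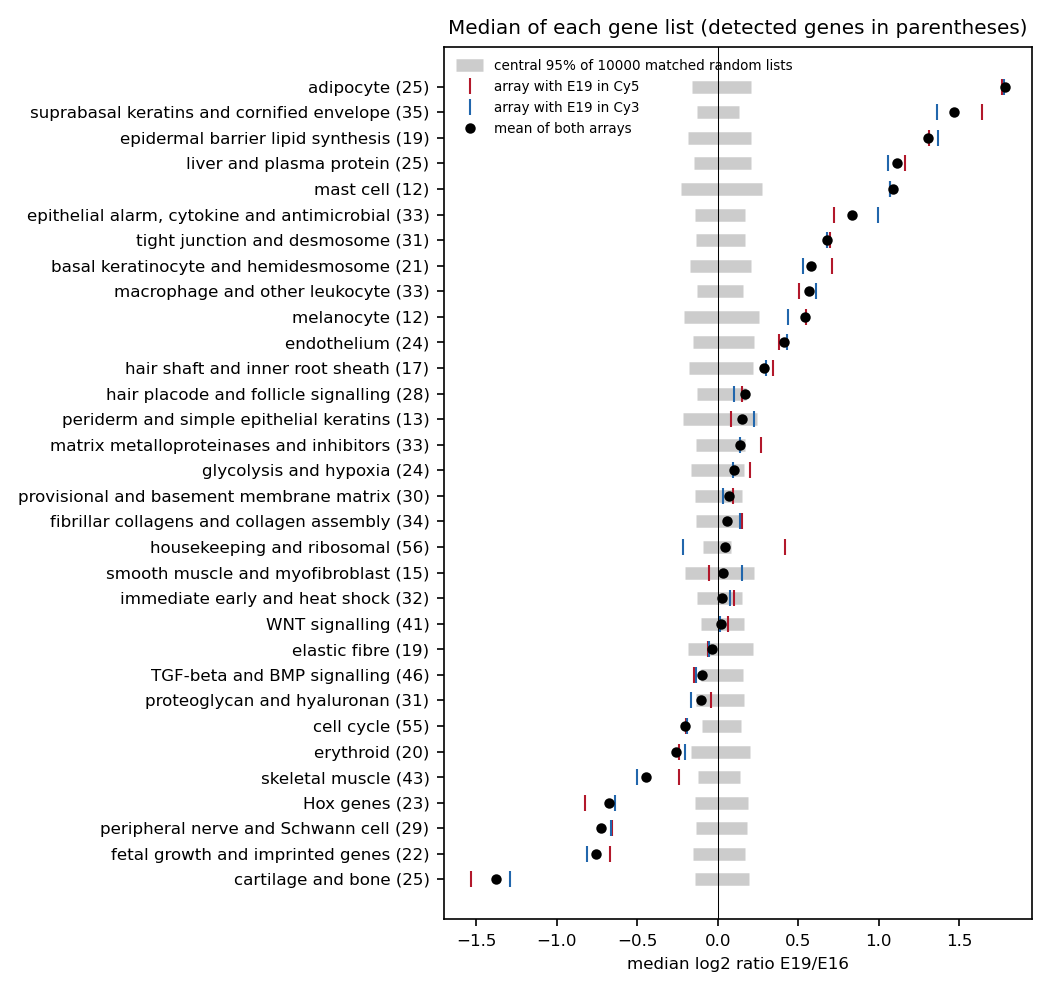
Median log2 ratio E19 over E16 (x axis) of each of 32 gene lists (y axis, number of detected genes in parentheses), with black points for the mean of both arrays, ticks for each array and grey bars for the central 95% of 10000 matched random lists. Adipocyte genes (1.79) lie highest and cartilage and bone genes (-1.38) lowest, and housekeeping and ribosomal genes lie on opposite sides of 0 on the 2 arrays.

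Cartilage and bone genes were higher in E16, with 15 of 25 past the rule in that direction, 0 in the other, and a median of -1.38 (0 percentile). Besides Cnmd, the largest ratios were of the bone sialoprotein gene Ibsp (-3.42 ± 0.37) and the cartilage collagens Col2a1 (-2.69 ± 0.24) and Col9a2 (-2.41 ± 0.20). The median was -2.20 with Feature Extraction's processed signals. Col2a1 was at -1.38 averaged over its 2 detected probes, so its dimmer probe alone did not pass the rule. Nerve and Schwann cell genes had a median of -0.72 (0 percentile), with 11 of 29 higher in E16, led by Stmn2 and Ina, the synaptic gene Snap25 (-3.22 ± 0.03) and the neuronal RNA-binding protein gene Elavl4 (-3.04 ± 0.10). Snap25 was at -4.48 with Feature Extraction's processed signals, and Elavl4 at -2.25 averaged over its detected probes. The neurofilament Nefh (1.27) and the transcription factor Pou3f1 (1.26) passed the rule towards E19.

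Hox genes, which pattern the body axis, had a median of -0.68 (0 percentile), and 7 of 23 were higher in E16 with 0 higher in E19. Hoxa9 (-2.40 ± 0.11), Hoxa5 (-2.14 ± 0.03), Hoxc6 (-1.91 ± 0.11) and Hoxa11 (-1.46 ± 0.09) had the largest ratios. Averaged over its 2 detected probes Hoxc6 was at -1.30, so its dimmer probe alone did not pass the rule. Fetal growth and imprinted genes had a median of -0.76 (0 percentile), with 4 of 22 higher in E16: the cell cycle inhibitor Cdkn1c (-2.03 ± 0.57), the insulin-like growth factor binding protein genes Igfbp5 (-1.98 ± 0.10) and Igfbp2 (-1.70 ± 0.19), and Grb10 (-1.29 ± 0.41). These groups moved with the cartilage list (median -1.38) and the nerve list (median -0.72) in the same pools.

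Skeletal muscle genes had a median of -0.45 (0 percentile) with members in both directions, 8 higher in E16 and 4 higher in E19 of 43. Myod1, which commits cells to muscle (-2.48 ± 0.02), and the slow myosin Myh7 (-1.78 ± 0.13) were higher in E16. The perinatal myosin Myh8 (1.80 ± 0.14) and the fast-fibre protein gene Mybpc2 (1.87 ± 0.17; 2.59 with Feature Extraction's processed signals) were higher in E19. Erythroid genes had a median of -0.26 (0.27 percentile), and the 3 past the rule of 20 were the globins Hbe1 (-3.34 ± 1.51), Hbg1 (-2.83 ± 0.02) and Hbe2 (-1.42 ± 0.12), all higher in E16. The brightest Hbe1 probe, saturated in 1 channel of the array with E19 in Cy3, read -2.27 with E19 in Cy5 and -4.41 with E19 in Cy3. The other Hbe1 probe, which takes its place when saturated spots are left out, read -4.14 and -4.69 on the same arrays. Cell cycle genes had a median of -0.20 (0.01 percentile), with 51 of 55 ratios below 0 and 0 past the rule. Ccne1, which encodes cyclin E1, came closest (-1.11 ± 0.40).

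Matrix genes as groups lay within chance. Fibrillar collagens had a median of 0.06, with only Col12a1 of 34 past the rule (-1.02 ± 0.02). Elastic fibre genes had a median of -0.03, with Efemp1 (1.69 ± 0.21) and Mfap5 (1.29 ± 0.20) higher in E19 and Ltbp1 higher in E16 (-1.38 ± 0.23). Proteoglycan and hyaluronan genes had a median of -0.10 (6.0 percentile), with 3 of 31 higher in E19 and 4 higher in E16, namely Fmod (-2.57 ± 0.09), Epyc (-1.94 ± 0.08), Kera (-1.68 ± 0.01) and Hapln1, beside a cartilage list median of -1.38. Hapln1 was well above background in the E19 pool on only 1 of 2 arrays, and its ratio was -1.67 in the main setting, -2.55 at normexp offset 0 and -3.39 with Feature Extraction's processed signals. With those signals Epyc was at -2.71 and Kera at -2.30. Provisional and basement membrane genes had a median of 0.07, and only Thbs4 of 30 passed the rule (-1.01).

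Matrix metalloproteinases and their inhibitors had a median of 0.14 (94.5 percentile) with 5 of 33 past the rule in each direction. Mmp13 and the stromelysin Mmp3 (3.27 ± 0.11) were higher in E19, and Mmp24 was higher in E16 (-2.32 ± 0.14). Mmp7 was not well above background in the E19 pool and was at least 3.97-fold higher in E16.

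TGF-beta and BMP signalling genes had a median of -0.10 (2.83 percentile), just within chance. The BMP inhibitors Grem1 (-1.82 ± 0.25) and Nog and the growth factor gene Tgfb2 (-1.17 ± 0.03) were higher in E16, and Id4 was higher in E19 (1.07 ± 0.09), of 46. WNT signalling genes had a median of 0.02, and 5 of 41 passed the rule, all towards E16, with Wnt5b (-1.27 ± 0.15), Sfrp5 (-1.23 ± 0.06) and Wnt2b (-1.13 ± 0.07) beside Dkk4. Smooth muscle genes (median 0.03) had only Tagln of 15 past the rule (-1.54 ± 0.30). Immediate early and heat shock genes (median 0.03) had the heat shock gene Hspa1a (1.47 ± 0.23) and Klf4 (1.46 ± 0.11) higher in E19. Glycolysis and hypoxia genes (median 0.10) had Ndrg1 higher in E19 (1.36 ± 0.10) and Aldoc higher in E16 (-1.09 ± 0.01).

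Housekeeping and ribosomal genes had a median of 0.04, and 0 of 56 passed the rule. Gapdh was at 0.02 ± 0.57 and Actb at -0.04 ± 0.92. Both genes were above 0 on the array with E19 in Cy5 and below 0 on the other. Only 1 sex-linked gene was detected, named Uty through the older name Utx (0.32 ± 0.04). That match is uncertain, since Utx is also used for an X-linked relative.

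Some genes were well above background in only 1 pool. Of these, Khdrbs2 was at least 9.01-fold, the glutamate receptor subunit Gria2 at least 9.42-fold, the opioid precursor Pdyn at least 7.75-fold, Rit2 at least 6.78-fold and the neuronal transcription factor Neurod1 at least 5.20-fold higher in E16. In the other direction, Xirp2 was at least 3.52-fold, Ankef1 at least 3.37-fold, Mmp10 at least 2.76-fold, the vitamin D binding protein gene Gc at least 2.71-fold and Oas1b at least 2.58-fold higher in E19.

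In the authors' deposited table, 1806 sequences were at least 2-fold higher in E19 and 2005 at least 2-fold higher in E16, each with the authors' p-value under 0.01. Of the 1167 genes past the rule here, 1160 were found in the authors' deposited table, 1160 of them with the same direction and 1147 at least 2-fold there. That table combines the same 2 arrays, and its direction was read from them, so this is no independent check.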

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

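Probes without a gene name entered no comparison of the report. Of 10228 detected, 595 were at least 2-fold on both arrays, with 151 higher in E19 and 444 higher in E16, against 0 towards the same dye on both.

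The 10 spike-in RNAs, control transcripts added with each dye, were not used for the ratios. Turned in the same way as the genes, they had a mean log2 ratio of 0.22 with an SD of 0.03 over the spike-ins, and 10 of 10 lay above 0. With Feature Extraction's own log ratios the mean was 0.21. Centring on the spike-ins therefore lowers every log2 ratio by that amount.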

How the results depend on the processing

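Medians of the lists beyond chance among those fixed beforehand kept their sign under every alternative run, and no named gene that passed the rule turned, but sizes moved. Counting each list or gene once per alternative, 210 list medians and 419 named-gene values moved by more than the SD of the 2 arrays, against 398 and 1472 that did not. By over 1.5 times as a fold, 2 lists and 34 named genes moved under at least 1 alternative. The lists were cartilage and bone (-2.20 with Feature Extraction's processed signals or log ratios, -2.10 in the authors' deposited table) and liver and plasma protein (1.83 with those signals or log ratios). Genes higher in E19 numbered 613 and in E16 554; these became 1014 and 889 with Feature Extraction's processed signals or its log ratios, 1189 and 995 at 2-fold in the authors' deposited table, 1413 and 1138 at 1.5-fold, and 178 and 230 at 3-fold. The fold limits change the count by construction. Removing only the normexp offset also raised the counts, to 776 and 772, and no background subtraction gave 676 and 647. The cause of the larger moves with Feature Extraction's values and in the authors' deposited table was not tested. Median centring in place of loess gave 367 genes higher in E19 and 439 higher in E16, so that the larger count changed sides, with 192 towards the same dye and r = 0.60 between the arrays. Centring on the spike-in RNAs, added after seeing the data, gave 389 higher in E19 and moved the median of all genes by -0.22; every ratio falls by that amount. Gapdh then lay below 0. Genes towards the same dye, 3 in the main setting, were 6 with outlier spots kept, 6 with spike-in centring, 11 when the mean ratio alone had to pass, 30 at 1.5-fold, 0 at 3-fold and 1 without the brightest genes. Lists beyond chance numbered 11 to 14 towards E19 and 7 to 10 towards E16. Setting list members measured in only 1 pool to their bounds left each list median at its printed value. A gene not well above background in a pool on either array is given as a bound, and Krt25 and Hapln1, measured in their dimmer pool on 1 of 2 arrays, as ratios.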

Other observations

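Among the tests below, those of hepatocyte genes, of neuronal cell body genes and of saturated spots were written before their results were seen; the others were chosen afterwards. The neuronal test was first worded for neural and skeletal tissue and was narrowed afterwards to neural tissue, the part it measures. All patterns were noticed in the data before they were tested.

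Of the 29 nerve and Schwann cell genes, 11 were higher in the E16 pool and 2 in the E19 pool. A dye bias is argued against, since the nerve list had a median of -0.66 even on the array with E19 in Cy3. A lower share of keratinocytes would by itself raise every other cell type in E16. Cartilage (-1.38) and skeletal muscle (-0.45) lists had medians towards E16, but endothelial (0.41) and macrophage (0.56) lists towards E19. This argues against that share as the only difference. Whether it contributes cannot be told, because other cell types can also change with stage. Neural tissue in the E16 samples may contribute: 32 detected genes of neuronal cell bodies and progenitors, 0 of them in the other lists, had a median of -0.76 (0 percentile), with 12 higher in E16 and 0 higher in E19, and 27 of the 32 were also well above background in E19. Among them Mapt (-2.22) and Stmn3 (-2.19) were higher in E16, while Tubb2b was at -0.22 ± 1.07 with the arrays on opposite sides of 0. A fall of these transcripts within skin nerves with stage stays open and untested, as does the source of the cartilage genes.

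Plasma protein genes were higher in the E19 pool. Erythroid genes without embryonic globins had a median of -0.17, so erythroid transcripts did not rise alongside. This cannot decide whether blood content was the source, because erythroid transcripts may themselves change with stage, as the embryonic globins did. Plasma proteins that blood carries as protein would not be measured by these arrays, which measured RNA. Hepatocytes in the E19 samples may contribute, but on weak evidence. The median of 34 other genes listed for hepatocytes was 0.20, the 99.8 percentile, with 4 higher in E19, 1 higher in E16 and 14 of the 34 below 0. That median is smaller than the spike-in offset of 0.22 and was -0.02 relative to the spike-ins, a shift that all genes and random lists share. The 4 were Arg1, Rbp2, Hpd and Gc, and the 1 was Asgr1 (-1.33). In the E16 pool, Arg1, Rbp2 and Hpd had higher log2 levels (12.46, 11.62 and 9.34) than Alb (8.75). Their rise need not come from hepatocytes. Of the liver and plasma protein list itself, 24 of 25 ratios lay above 0 and 12 passed the rule towards E19, while Ttr (-2.01), Apob (0.01) and Hp (0.09) did not follow Alb. Expression of plasma protein genes by the skin itself was not tested.

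The 2 arrays differed for the brightest genes. For 345 genes with a mean log2 intensity over 16, the Cy5 over Cy3 component of the ratio had a median of 0.29, against -0.01 for genes between 10 and 14. This is consistent with a dye effect that depends on intensity and that loess left in place, since with Feature Extraction's own log ratios the median was 0.07. Leaving out saturated spots gave 0.28 over 335 genes, so flagged spots do not account for this median. So few were flagged that leaving them out could hardly move it. Signal compressed just under the flag was not tested. Among the 345 bright genes, 10 had a mean ratio past 2-fold without passing on both arrays. No biological explanation was tested.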
